A study of Mus musculus with 12 samples.

How the data were processed

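RNA was measured in the apical and middle turns of the cochlea of mice at postnatal day 7, with at least 6 cochleae pooled per sample, per the labels. The 12 samples form 4 groups of 3: Control, β-catenin OE (overexpression), Notch1 KO (knockout), and both changes together, called the double group here. Groups and sample numbers come from the sample titles. The labels do not say that samples of a group came from separate pools of animals, so p-values measure only the spread between these samples, which may be technical in part. Sex-linked genes, reported below, argue against all samples of a group coming from the same pool.

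The values are FPKM (fragments per kilobase of transcript, scaled to the mapped fragments of the library) made by the authors and deposited as 1 table for the whole series. The submitters' processing notes name CASAVA 1.8, Trimmomatic 0.23, TopHat2 2.0.10, Bowtie2 2.2.1, Cufflinks 2.2.1 and Cuffdiff and the mouse build mm10, without role or order. The annotation, any filter and any further scaling between libraries are not given in the sources used here. The deposited table also holds the authors' log2 fold changes against Control and the authors' p-values for 3 comparisons, with a lowest p-value of 5e-05. It has 23598 rows. In it 514 symbols stand in more than 1 row and 647 rows merge several genes. Where a symbol had several rows, the row with the highest mean kept the plain symbol. Loci in the table start 1 base lower than a browser shows, so 1 was added to each start.

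Tests were run with limma 3.58.1 in R 4.3.3 on log2(FPKM + 0.5), over 14581 rows with an FPKM of at least 0.5 in at least 3 samples. All 12 samples entered 1 model of the 4 group means with a trended empirical Bayes spread. P-values are two-sided, adjusted by Benjamini-Hochberg within a comparison, with a threshold of 0.05. Fold changes are on the log2(FPKM + 0.5) scale, which understates the change of low genes, and ± beside them is the standard error. An exact 0 can be a failed estimate. FPKM values allow no count test, so tools for counts were not run.

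The 34 gene lists were fixed before the data were examined, as were the design, the first set of other settings and the rule for named genes. That rule takes Notch1 and Ctnnb1, then up to 8 rising and 8 falling genes by size among those past the threshold, with a mean of at least 1 FPKM in 1 group and no overlap between samples. It leaves out predicted models and ribosomal or small RNA, and adds up to 4 members with the smallest p of each list that passed or holds a called member. Some genes the rule names are not reported here. Some lists share members, so their results are not independent. The supporting cell list shares Lfng, Hes5 and Hey2 with the Notch targets and Lgr5 and Prox1 with the Wnt targets. Of the lists, 33 had at least 3 tested members, and the mitochondrially encoded list had none. They were tested with camera at a preset inter-gene correlation of 0.01. Lists past the threshold numbered 9, 15, 16, 16, 15 and 12 in the 6 comparisons, in the order of the results. With a correlation estimated from the data they numbered 1, 4, 1, 0, 1 and 0.

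Depth is not given in the table. In genes with 1 annotated transcript (GENCODE M21, 2742 genes over 1 kb), low values of the 8 samples numbered 2 and 3 lay on steps of whole fragments. Between 76.5% and 81.6% of their values below 5.5 fragments were within 0.1 of a whole number, where chance gives 20% before fitting. Depth and a length offset were fitted in each sample to bring these same values closest to whole numbers. The share by chance after fitting can be higher and was not estimated. The spacing of the steps gives the depth if FPKM was not scaled further between libraries, which is not known. In the 4 samples numbered 1 the share was 26.8% to 40%, so their depth is unknown.

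Samples 2 and 3 of a group were far closer to each other than to sample 1. Over 5889 genes of at least 10 FPKM in all samples, the robust SD of the log2 difference was 0.0744 to 0.131 between samples 2 and 3 and 0.287 to 0.438 against sample 1. Squared differences of samples 2 and 3 were 1.48 to 1.83 times counting noise at 20 to 100 fragments, 1.6 to 2.37 at 100 to 500 and 2.32 to 5.01 at 500 or more, and they were kept as separate samples. Whether they are separate pools of animals is not known, and where they are not, the p-values here are too small. On simulated data with 3 independent samples per group and no changed gene, 0 genes were called for β-catenin OE against Control, and 69% of genes changed by 1 on the log2 scale and 96% of those changed by 2 were recovered. Another simulation gave samples 2 and 3 the correlation seen in the data (0.906), and a further one also gave the samples numbered 1 their mean correlation between groups (0.35). Both were drawn 1 time. With changed genes, for β-catenin OE against Control, 71.1% of 599 calls were false in the former and 46.2% of 305 in the latter. With 3 independent samples 7.3% of 178 calls were false.

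Sample numbers were checked for pairing by the correlation, across tested genes, of same-numbered samples' deviations from their group means. In 5 of the 6 pairs of groups all 3 correlations were over 0.1. The exception was β-catenin OE with the double group, at 0.28, 0.06 and 0.23. Among 12891 genes above 0.5 FPKM in all samples the exception was Control with Notch1 KO instead, where number 3 had 0.03. Unlike numbers, 2 of 1 group with 3 of another, had 0.0358 to 0.322 across tested genes, often as high as like numbers. Since samples 2 and 3 of a group were nearly alike, such values can arise with or without pairs. Unlike numbers with sample 1 were not compared, so whether like numbers are pairs stays open. Genes are not independent replicates. Alternatives covered the pseudocount, filter, scaling, replicate block, spread, threshold and leaving out each sample. A batch term for sample 1, averaging samples 2 and 3, using them alone, leaving out merged and small RNA rows, and leave-one-out for the lists were added after seeing the data.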

Results

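The series measured RNA in the postnatal mouse cochlea after genetic changes to 2 pathways: Wnt, through β-catenin (Ctnnb1), and Notch, through the receptor Notch1. Its design text names proliferation of supporting cells and the making of hair cells, the sensory cells of hearing, as the subject. There were 4 groups of 3 samples: Control, β-catenin OE, Notch1 KO and the double group. Fold changes are log2 values with their standard error (n = 3 per group), and adjusted p-values are limma's with Benjamini-Hochberg adjustment. Depth by the whole-fragment steps, in units of 1e6 fragments, was 18.8 and 26.9 in Control samples 2 and 3, 20.2 and 25 in β-catenin OE, 21.6 and 19.6 in Notch1 KO and 24.4 and 19.4 in the double group. These depths hold only if FPKM was not scaled further between libraries. Depth is unknown for the 4 samples numbered 1.

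Notch1 (chromosome 2, 26457674 to 26503822, mm10) had FPKM values of 24.3, 14.7 and 16.6 in Control, 37.6, 15.7 and 16.7 in β-catenin OE, 9.16, 7.63 and 7.56 in Notch1 KO and 8.62, 5.7 and 5.77 in the double group. Each Notch1 KO and double sample lay below every sample of Control and β-catenin OE. The fall passed the test in the double group against Control (-1.39 ± 0.30, adjusted p = 0.0113) and against β-catenin OE (-1.64 ± 0.30, adjusted p = 0.0175). Both calls ended with samples 2 and 3 averaged. The call against β-catenin OE also ended in a model of the 2 groups alone, and with all 4 groups it ended without double sample 2 (-1.54) and without double sample 3 (-1.55). In Notch1 KO against Control the difference was -1.11 ± 0.30 (adjusted p = 0.16) and did not pass, though it passed with the replicate block, with a batch term for sample 1, with samples 2 and 3 alone and without β-catenin OE sample 1. Ctnnb1 (chromosome 9, 120933363 to 120960513) had 392 ± 37.5 FPKM (SD, n = 3) in Control, 398 ± 22.5 in β-catenin OE, 379.9 ± 4.93 in Notch1 KO and 454 ± 40.4 in the double group, and with all 12 samples passed in none of the 6 comparisons. The table gives no value per exon, so a change within the Ctnnb1 transcript was not analysed here.

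**Figure D1:**
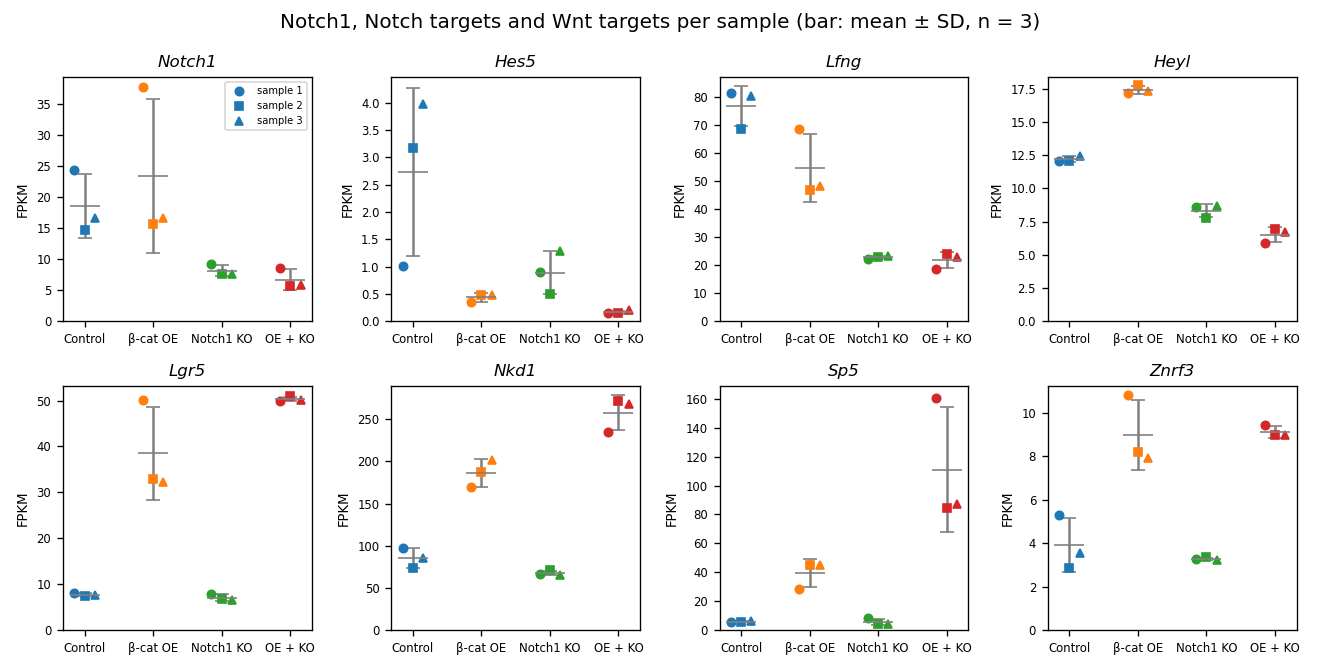
FPKM per sample (y axis, linear, from 0) of 8 genes in the 4 groups (x axis); points are samples, and grey bars are the mean ± SD (n = 3). Lgr5 lies at 7.48 to 8.07 FPKM in Control and 32.3 to 50.1 in β-catenin OE.

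In β-catenin OE against Control, 5 of 28 genes known as Wnt targets rose. Lgr5 (chromosome 10, 115450195 to 115587780), a receptor of Wnt-responsive progenitors, went from 7.75 ± 0.301 to 38.5 ± 10.1 FPKM (SD, n = 3; 2.21 ± 0.15, adjusted p = 2.34e-05). Nkd1 and Znrf3, feedback inhibitors of Wnt signalling, and the transcription factor Sp5 rose by 1.11, 1.13 and 2.59. In the Wnt target list, of 28 tested members, 5 rose, 0 fell and 23 did not pass, and adjusted over the list alone, 12 rose and 0 fell (median log2 fold change 0.47, camera adjusted p = 1.51e-10, and adjusted p = 0.0227 with an estimated correlation). Il17rd (0.77 ± 0.12), Etv4 (0.98 ± 0.18) and Spred2 (0.51 ± 0.11) of the FGF signalling list rose. Of 17 tested members, 3 rose, 0 fell and 14 did not pass, and adjusted over the list alone, 8 rose and 1 fell (adjusted p = 0.115 with an estimated correlation).

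The largest rises by the naming rule were in Prss56 (5.24 ± 0.42), the Wnt antagonist Dkk4 (5.22 ± 1.06), Tprg (4.90 ± 0.32) and Dpp6 (4.07 ± 0.28). Dkk4 had 1.18 FPKM in β-catenin OE sample 1 and 66.1 and 63.2 in samples 2 and 3, while all Control samples were at or below 0.0509. Falls were led by the transporter Slc22a3 (-2.42 ± 0.22), Agr3 (-2.38 ± 0.34), and the nicotinic receptor subunits Chrna3 (-2.20 ± 0.35) and Chrnb4 (-1.98 ± 0.22). Among Notch targets Heyl rose (0.50 ± 0.10) and Hes5 fell (-1.64 ± 0.35). In the supporting cell list, of 27 tested members, 4 rose, 5 fell and 18 did not pass, and adjusted over the list alone, 4 rose and 6 fell. No member of the early or maturing hair cell lists passed limma's test, and at an unadjusted p under 0.05 3 of 16 and 4 of 40 differed. Of G2M phase genes, active in dividing cells, 0 of 36 passed limma's test and 20 had an unadjusted p under 0.05, although the list passed (median log2 fold change 0.95, camera adjusted p = 3.59e-13, and adjusted p = 0.667 with an estimated correlation). Their median was -0.40 in sample 1 against Control sample 1 and 1.55 in samples 2 and 3. Mki67, chosen after its values were seen, had 1.09, 4.56 and 4.52 FPKM in the 3 β-catenin OE samples.

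By limma, 327 of 14581 genes passed, 199 higher and 128 lower, and over all tested genes the log2 fold changes of the samples numbered 1 and of samples 2 and 3 had a correlation of 0.20. Other lists past camera's threshold, with median log2 fold changes in the samples numbered 1 and in samples 2 and 3, were hair cell maturing (0.13 and -0.41), S phase (-0.32 and 0.56), Schwann and myelinating glia (-0.58 and 1.44), bone and cartilage (-0.98 and -0.50), macrophage and immune (-1.87 and 0.04) and interferon response (-2.08 and -0.35). Their adjusted p was 0.667 to 0.888 with an estimated correlation. The count was 10 with samples 2 and 3 of each group averaged into 1 value and 635 with the sample number as a replicate block. It was 901 without Control sample 1, 149 without Control sample 2, 149 without Control sample 3, 875 without β-catenin OE sample 1, 126 without β-catenin OE sample 2 and 128 without β-catenin OE sample 3.

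Hair cell genes rose in Notch1 KO against Control. The transcription factor Gfi1 (chromosome 5, 107716653 to 107725805; 1.04 ± 0.14) and Rasd2 (1.38 ± 0.17) of the early list rose, as did the hair bundle genes Grxcr2 (1.29 ± 0.18), Loxhd1 (1.23 ± 0.17), Lhfpl5 (1.06 ± 0.17) and Ptprq (1.11 ± 0.18) of the maturing list. In the early list, of 16 tested members, 5 rose, 0 fell and 11 did not pass, and adjusted over the list alone, 13 rose and 1 fell (adjusted p = 0.0185 with an estimated correlation). In the maturing list, of 40 tested members, 9 rose, 0 fell and 31 did not pass, and adjusted over the list alone, 25 rose and 0 fell (median log2 fold change 0.68, camera adjusted p = 7.04e-32, and adjusted p = 0.0185 with an estimated correlation). The maturing list's median was 0.90 in the samples numbered 1 and 0.66 in samples 2 and 3.

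Notch targets fell in Notch1 KO, with Lfng (chromosome 5, 140603667 to 140615679; -1.72 ± 0.15, adjusted p = 0.00159), Heyl (-0.53 ± 0.10) and Hey1 (-0.83 ± 0.16) past the test. Of 10 tested members, 0 rose, 3 fell and 7 did not pass, and adjusted over the list alone, 0 rose and 4 fell (adjusted p = 0.0185 with an estimated correlation). The list's median was -0.14 in the samples numbered 1, with 4 of 10 genes higher, and -0.37 in samples 2 and 3, with 1 higher. In the supporting cell list Lfng, the same gene as among the Notch targets, and Trh (-1.98 ± 0.31) fell. Of 27 tested members, 0 rose, 2 fell and 25 did not pass, and adjusted over the list alone, 0 rose and 7 fell (adjusted p = 0.0185 with an estimated correlation). The supporting cell median was -0.11 in the samples numbered 1, with 10 of 27 genes higher, and -0.31 in samples 2 and 3, with 7 higher. The Wnt target Notum fell (-0.68 ± 0.12). Other rising genes were Gng8 (2.37 ± 0.31) and Grp (2.14 ± 0.23), and other falling genes Agr3 (-2.54 ± 0.34), Prdm12 (-2.28 ± 0.21) and Crhr1 (-2.13 ± 0.23). No S or G2M phase gene passed limma's test, and 0 and 1 had an unadjusted p under 0.05. Limma called 125 genes, 78 higher and 47 lower, and over all tested genes the log2 fold changes of the samples numbered 1 and of samples 2 and 3 had a correlation of 0.20. Other lists past camera's threshold, with median log2 fold changes in the samples numbered 1 and in samples 2 and 3, were Wnt targets (-0.25 and -0.06), Wnt ligands, receptors and core components (-0.13 and -0.11), G2M phase (0.09 and 0.36), melanocyte (-0.42 and 0.50), mesenchyme and fibroblast (-0.85 and 0.02), bone and cartilage (-2.22 and -0.14), osteoclast (-0.55 and -0.70), macrophage and immune (-2.01 and -0.11), endothelial and pericyte (-1.10 and 0.12), interferon response (-1.81 and 0.02) and circadian clock (-0.69 and 0.01). Their adjusted p was 0.0943 to 0.89 with an estimated correlation. The count was 0 with samples 2 and 3 of each group averaged into 1 value and 237 with the sample number as a replicate block. It was 43 without Control sample 2, 54 without Control sample 3, 213 without β-catenin OE sample 1, 55 without Notch1 KO sample 1, 28 without Notch1 KO sample 2, 14 without Notch1 KO sample 3 and 72 without double sample 2.

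**Figure D2:**
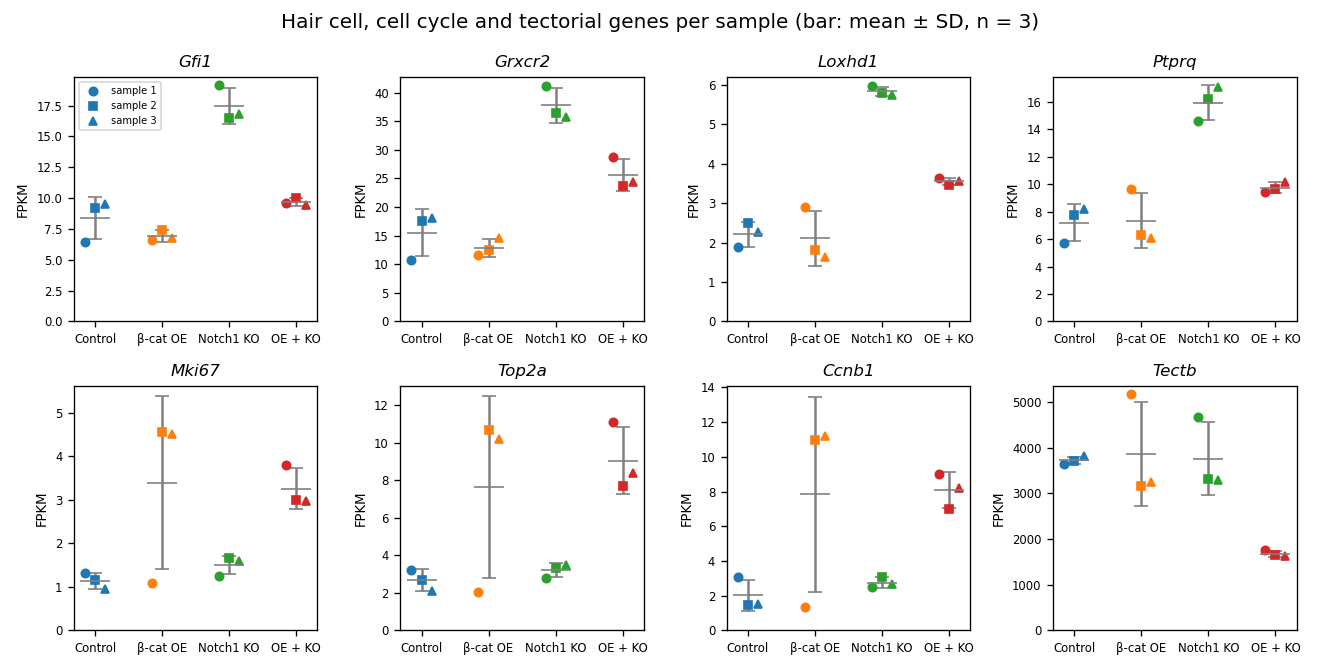
FPKM per sample (y axis, linear, from 0) of 8 genes in the 4 groups (x axis); points are samples, and grey bars are the mean ± SD (n = 3). Mki67, chosen after its values were seen, lies at 1.09 FPKM in β-catenin OE sample 1 and at 4.52 and 4.56 in samples 3 and 2.

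In the double group against Control, 15 of 36 cell division genes of the G2M list rose. They included Nek2 (1.43 ± 0.30), Plk1 (1.63 ± 0.35), Cenpf (1.12 ± 0.27) and Aurka (1.23 ± 0.30). Of 36 tested members, 15 rose, 0 fell and 21 did not pass, and adjusted over the list alone, 32 rose and 0 fell (median log2 fold change 1.35, camera adjusted p = 2.24e-13, and adjusted p = 0.44 with an estimated correlation). In the list of cell cycle inhibitors and D cyclins, of 16 tested members, 3 rose, 1 fell and 12 did not pass, and adjusted over the list alone, 3 rose and 1 fell, with Ccnd1 (1.72 ± 0.31) higher and the inhibitor Cdkn1b (-0.81 ± 0.12) lower. That list did not pass camera's test (adjusted p = 0.0634). Among Wnt targets Sp5 (4.03 ± 0.28), Lgr5 (2.62 ± 0.15), Nkd1 (1.58 ± 0.12) and Tcf7 (1.45 ± 0.17) rose. Of 28 tested members, 16 rose, 2 fell and 10 did not pass, and adjusted over the list alone, 18 rose and 3 fell (adjusted p = 0.0451 with an estimated correlation). FGF signalling genes Il17rd (1.31 ± 0.12) and Etv4 (1.60 ± 0.18) rose and Fgfr2 fell (-0.93 ± 0.12). Of 17 tested members, 9 rose, 2 fell and 6 did not pass, and adjusted over the list alone, 10 rose and 2 fell (adjusted p = 0.19 with an estimated correlation).

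Notch targets Lfng (-1.79 ± 0.15), Hes5 (-2.13 ± 0.35), Hey1 (-1.34 ± 0.16) and Heyl (-0.86 ± 0.10) fell. Of 10 tested members, 1 rose, 4 fell and 5 did not pass, and adjusted over the list alone, 1 rose and 4 fell (adjusted p = 0.19 with an estimated correlation). Early hair cell genes Rasd2 (1.02 ± 0.17) and Hes6 (1.03 ± 0.18) rose. Of 16 tested members, 3 rose, 0 fell and 13 did not pass, and adjusted over the list alone, 4 rose and 0 fell (adjusted p = 0.385 with an estimated correlation). In the maturing list Grxcr2 (0.74 ± 0.18) rose while Clic5 (-0.83 ± 0.13) fell. Of 40 tested members, 3 rose, 2 fell and 35 did not pass, and adjusted over the list alone, 3 rose and 2 fell. More supporting cell genes fell than rose, such as Cyp26b1, a retinoic acid degrading enzyme (-2.93 ± 0.27). Of 27 tested members, 3 rose, 13 fell and 11 did not pass, and adjusted over the list alone, 3 rose and 15 fell (adjusted p = 0.19 with an estimated correlation). Tectb, a protein of the tectorial membrane, fell (-1.15 ± 0.24), as did the neuronal gene Syt1 (-1.55 ± 0.11) and S100b (-1.82 ± 0.18).

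In all, 1826 genes passed limma's test, 858 higher and 968 lower, and over all tested genes the log2 fold changes of the samples numbered 1 and of samples 2 and 3 had a correlation of 0.54. Other lists past camera's threshold, with median log2 fold changes in the samples numbered 1 and in samples 2 and 3, were S phase (0.64 and 0.46), stria vascularis and ion transport (-0.22 and -0.40), spiral ganglion neuron (-1.47 and 0.03), mesenchyme and fibroblast (-0.50 and -0.31), bone and cartilage (-2.42 and -0.44), osteoclast (-0.81 and -0.33), immediate early and dissection stress (0.38 and 0.28), interferon response (-0.98 and -0.67), circadian clock (-0.74 and -0.07) and ribosomal proteins (0.44 and 0.29). Their adjusted p was 0.19 to 0.58 with an estimated correlation. Double samples 2 and 3 had 0.0239 and 0.0146 FPKM of Xist, a transcript of female cells chosen after its values were seen, against 19.5 in double sample 1 and 25.6 to 84.5 in Control. The count was 259 with samples 2 and 3 of each group averaged into 1 value and 2934 with the sample number as a replicate block. It was 1128 without double sample 2 and 1198 without double sample 3.

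β-catenin OE and the double group were compared with the same Control samples. Across genes their log2 fold changes had a correlation of 0.69 and a covariance of 0.156. Simulated unchanged groups of independent samples, with a shared Control, gave 0.49 and 0.0384. A shared pool of samples 2 and 3 was not simulated for these values. The share of genes with the same sign in both comparisons was 68.5%, little above the 66.7% of the simulated groups. Both comparisons called 178 genes higher and 108 lower, and 2 in opposite directions. With no changed gene and a shared Control, 50 simulations of 3 independent samples shared 0 calls. When samples 2 and 3 shared a pool they shared 19 to 45 calls higher, 20 to 49 lower and 0 to 3 in opposite directions.

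Against β-catenin OE, in the comparison that adds Notch1 KO, 3 of 10 Notch targets fell and 4 of 16 early hair cell genes rose in the double group. Heyl (-1.36 ± 0.10), Lfng (-1.29 ± 0.15) and Hey1 (-0.68 ± 0.16) fell. In the Notch target list, of 10 tested members, 0 rose, 3 fell and 7 did not pass, and adjusted over the list alone, 1 rose and 3 fell (adjusted p = 0.135 with an estimated correlation). Rasd2 (1.39 ± 0.17) and Dlk2 (1.14 ± 0.24) of the early list and Grxcr2 (0.97 ± 0.18) of the maturing list rose. In the early hair cell list, of 16 tested members, 4 rose, 0 fell and 12 did not pass, and adjusted over the list alone, 9 rose and 0 fell (adjusted p = 0.156 with an estimated correlation). In the maturing list, of 40 tested members, 1 rose, 0 fell and 39 did not pass, and adjusted over the list alone, 11 rose and 0 fell (adjusted p = 0.402 with an estimated correlation). In the supporting cell list, of 27 tested members, 0 rose, 6 fell and 21 did not pass, and adjusted over the list alone, 3 rose and 9 fell (adjusted p = 0.135 with an estimated correlation). The Notch ligand Jag1 fell (-0.85 ± 0.14), and among Wnt targets Sp5 (1.44 ± 0.28) and Wif1 (1.17 ± 0.26) rose.

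The neuronal genes Syt1 (-0.99 ± 0.11) and Gap43 (-0.97 ± 0.22) and the glial gene S100b (-0.78 ± 0.18) fell in the double group against β-catenin OE. In the spiral ganglion neuron list, of 18 tested members, 0 rose, 2 fell and 16 did not pass, and adjusted over the list alone, 0 rose and 8 fell (adjusted p = 0.398 with an estimated correlation). In the glial list, of 16 tested members, 0 rose, 1 fell and 15 did not pass, and adjusted over the list alone, 0 rose and 11 fell (adjusted p = 0.438 with an estimated correlation). No G2M gene passed limma's test, and 0 had an unadjusted p under 0.05. The G2M median was 1.88 in the samples numbered 1 and -0.34 in samples 2 and 3, opposite in sign (adjusted p = 0.702 with an estimated correlation). Limma called 396 genes, 178 higher and 218 lower, and over all tested genes the log2 fold changes of the samples numbered 1 and of samples 2 and 3 had a correlation of 0.35. Other lists past camera's threshold, with median log2 fold changes in the samples numbered 1 and in samples 2 and 3, were Wnt targets (0.38 and 0.21), prosensory and otic transcription factors (0.02 and -0.26), S phase (0.98 and -0.12), tectorial membrane and otic matrix (-0.62 and -0.29), mesenchyme and fibroblast (-0.24 and -0.25), macrophage and immune (1.59 and 0.00), erythroid (-1.68 and -0.82), circadian clock (-0.81 and -0.25) and ribosomal proteins (0.49 and 0.10). Their adjusted p was 0.316 to 0.686 with an estimated correlation. The count was 0 with samples 2 and 3 of each group averaged into 1 value and 826 with the sample number as a replicate block. It was 1023 without Control sample 1, 169 without β-catenin OE sample 2, 211 without β-catenin OE sample 3, 238 without Notch1 KO sample 2, 243 without Notch1 KO sample 3, 245 without double sample 1, 113 without double sample 2 and 131 without double sample 3.

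In the double group against Notch1 KO, which adds β-catenin OE, 18 of 28 Wnt targets rose and 11 of 40 maturing hair cell genes fell. Lgr5 (2.75 ± 0.15), Sp5 (4.12 ± 0.28), Nkd1 (1.92 ± 0.12) and Wif1 (2.36 ± 0.26) rose. Of 28 tested members, 18 rose, 1 fell and 9 did not pass, and adjusted over the list alone, 19 rose and 1 fell (adjusted p = 0.00964 with an estimated correlation). The growth factor Fgf20 (4.95 ± 0.84) and Il17rd (1.18 ± 0.12) rose. In FGF signalling, of 17 tested members, 9 rose, 1 fell and 7 did not pass, and adjusted over the list alone, 10 rose and 1 fell (adjusted p = 0.196 with an estimated correlation). Gfi1 (-0.82 ± 0.14) and Dlk2 (-0.94 ± 0.24) of the early hair cell list fell. Of 16 tested members, 2 rose, 4 fell and 10 did not pass, and adjusted over the list alone, 2 rose and 6 fell (adjusted p = 0.499 with an estimated correlation). Clic5 (-1.01 ± 0.13) and Acbd7 (-0.82 ± 0.17) of the maturing list fell. In that list, of 40 tested members, 0 rose, 11 fell and 29 did not pass, and adjusted over the list alone, 0 rose and 20 fell (adjusted p = 0.207 with an estimated correlation).

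G2M genes passed as a list (median log2 fold change 1.01, camera adjusted p = 2.15e-11, and adjusted p = 0.499 with an estimated correlation). Of 36 tested members, 0 rose, 0 fell and 36 did not pass (at an unadjusted p under 0.05, 29 differed), and adjusted over the list alone, 22 rose and 0 fell. Penk (-3.68 ± 0.41), Chrna3 (-2.90 ± 0.35) and Chrnb4 (-2.58 ± 0.22) fell. In the stria vascularis and ion transport list, of 15 tested members, 0 rose, 6 fell and 9 did not pass, and adjusted over the list alone, 1 rose and 11 fell (adjusted p = 0.207 with an estimated correlation), with Cldn11 (-1.20 ± 0.23) and Kcnq1 (-0.97 ± 0.20) among those that fell. Limma called 1476 genes, 716 higher and 760 lower, and over all tested genes the log2 fold changes of the samples numbered 1 and of samples 2 and 3 had a correlation of 0.69. Other lists past camera's threshold, with median log2 fold changes in the samples numbered 1 and in samples 2 and 3, were prosensory and otic transcription factors (-0.20 and -0.23), S phase (0.54 and 0.46), cell cycle inhibitors and D cyclins (0.28 and 0.20), melanocyte (-0.08 and -1.02), spiral ganglion neuron (-0.22 and -0.26), macrophage and immune (1.45 and 0.19), neutrophil and bone marrow (-0.03 and 1.17), immediate early and dissection stress (0.36 and 0.33) and ribosomal proteins (0.18 and 0.29). Their adjusted p was 0.207 to 0.694 with an estimated correlation. The count was 175 with samples 2 and 3 of each group averaged into 1 value and 2290 with the sample number as a replicate block. It was 790 without Notch1 KO sample 2, 808 without Notch1 KO sample 3, 872 without double sample 2 and 888 without double sample 3.

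The interaction asks whether the 2 changes add on the log2 scale. Limma called 3 genes: Ivl, a protein of the skin barrier (chromosome 3, 92570900 to 92613461; 2.08 ± 0.24, adjusted p = 0.0166), and Ism1 (chromosome 2, 139673442 to 139758774; 1.75 ± 0.19, adjusted p = 0.0166) were above the sum of the single effects, and Aldh1a2, an enzyme of retinoic acid synthesis (chromosome 9, 71215789 to 71296243; -1.79 ± 0.24, adjusted p = 0.049), was below it. At an unadjusted p under 0.05 there were 1226 genes, and over all tested genes the log2 fold changes of the samples numbered 1 and of samples 2 and 3 had a correlation of 0.20. Of 28 Wnt targets, 0 passed limma's test, 13 had an unadjusted p under 0.05 and, adjusted over the list alone, 5 lay above the sum of the single effects and 0 below it (median log2 fold change 0.42, camera adjusted p = 1.42e-06, and adjusted p = 0.107 with an estimated correlation). Other lists past camera's threshold, with median log2 fold changes in the samples numbered 1 and in samples 2 and 3, were hair cell maturing (-0.80 and -0.15), prosensory and otic transcription factors (-0.23 and -0.23), S phase (0.82 and -0.10), tectorial membrane and otic matrix (0.00 and -0.37), stria vascularis and ion transport (-0.24 and -0.17), melanocyte (0.03 and -0.74), spiral ganglion neuron (-0.28 and -0.56), Schwann and myelinating glia (0.32 and -1.53), macrophage and immune (3.62 and 0.30), erythroid (-2.08 and -0.65) and interferon response (2.55 and -0.31). Their adjusted p was 0.21 to 0.731 with an estimated correlation. The count was 0 with samples 2 and 3 of each group averaged into 1 value and 53 with the sample number as a replicate block. It was 67 without Control sample 1, 0 without Control sample 2, 0 without Control sample 3, 28 without β-catenin OE sample 1, 1 without β-catenin OE sample 2, 0 without β-catenin OE sample 3, 12 without Notch1 KO sample 1, 0 without Notch1 KO sample 2, 0 without Notch1 KO sample 3, 9 without double sample 1, 0 without double sample 2 and 0 without double sample 3.

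P-values take the samples of a group as independent, and samples 2 and 3 were nearly alike. Simulated data with no changed gene, in which samples 2 and 3 shared a pool, gave 277 calls for β-catenin OE against Control, where the data gave 327, 300 for Notch1 KO against Control (125 in the data) and 205 for the double group against Control (1826). For the double group the simulation gave 339 calls against β-catenin OE (396 in the data) and 378 against Notch1 KO (1476), and 355 for the interaction (3). Calls for Notch1 KO and the interaction were thus fewer than such a shared pool gave without any change. That simulation did not match the data there, nor for β-catenin OE against Control. For Notch1 KO and the interaction it put 19.3% and 19.1% of unchanged genes under an unadjusted p of 0.05. The data had 1206 and 1226 of 14581 genes there. For β-catenin OE against Control it put 19.2% there, where the data had 2035 genes. For the double group against β-catenin OE it put 19% there, and the data had 2653 genes, also fewer. Whether the calls of these comparisons exceed those without any change therefore cannot be judged from it. When the samples numbered 1 also shared a batch, the calls were 55, 4, 61, 55, 27 and 64 in the same order, and with 3 independent samples they were 0 in each.

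In the authors' deposited table, 304 of the 327 genes called here for β-catenin OE had an unadjusted p under 0.05, as did 114 of 125 for Notch1 KO and 1656 of 1826 for the double group. Both rest on the same samples.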

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

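The tests of explanations here were chosen after the results were seen; the counts of other splits were planned. For 3 genes the effect of 1 change differed by the other, by limma's interaction term: Ivl (2.08), Ism1 (1.75) and Aldh1a2 (-1.79). Of 100 drawn regroupings of the 12 samples, the real one included, 6 called at least 3 genes, and the highest other called 1410, so chance is not excluded for these 3 genes. So high a count points to a structure of the samples, which could be the differences between the groups themselves, and which structure it is was not tested.

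Each comparison of 2 groups has 10 splits of its 6 samples, too few for a share under 0.05. The real split alone (1 of 10) reached its own count in every one. The real and highest other counts were 327 and 2 for β-catenin OE, 125 and 0 for Notch1 KO and 1826 and 0 for the double group, each against Control. They were 396 and 1 for the double group against β-catenin OE, and 1476 and 0 against Notch1 KO. Splits mix groups that differ, which widens the spread and lowers their counts.

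Samples 2 and 3 of each group lay far closer to each other than to sample 1. A single library sequenced for both stays open: their squared differences were at least 1.48 times counting noise at 20 to 100 fragments and at least 2.32 times at 500 or more, but the error of estimating FPKM, which counting noise leaves out, is not known. Whole-fragment steps were sharper in all 8 samples numbered 2 or 3 than in the 4 numbered 1, by at least 36.6 percentage points, which is consistent with samples numbered 1 having been made or processed another way. The sex-linked genes reported below argue against sample 1 coming from the same pool of animals as samples 2 and 3 of its group. Whether samples 2 and 3 are libraries of 1 pool of RNA stays open, and no biological explanation was tested.

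G2M genes were higher in β-catenin OE samples 2 and 3 and not in sample 1. A sample 1 wholly without the β-catenin change is argued against. With the cell cycle lists left out, 715 genes rose in the double group against Notch1 KO. Lgr5 was 50.1 FPKM in β-catenin OE sample 1 against 8.07 in Control sample 1. Between these samples the 715 genes had a median log2 difference of 0.25, with 75.2% higher against 49% of all genes. The spread behind their call included the β-catenin OE samples, which favours genes alike in sample 1 and samples 2 and 3. That median is small, 17 of 28 Wnt targets were higher, and Dkk4 was 1.18 FPKM against 63.2 and 66.1 in samples 3 and 2, so a partly mixed sample stays open. Evenly weaker activation predicts a G2M median of 0.62, and the value seen lay -1.02 from it. In the samples numbered 1 the double group did show such a difference, with a G2M median of 1.48. Double sample 1 also differed from Control sample 1 in the Y-linked gene Ddx3y. Whether β-catenin OE sample 1 could show the difference is thus not settled. The timing and sex of the pools stay open and untested.

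Hair cell genes were higher in Notch1 KO. Less surrounding tissue in the dissection would raise supporting cell genes alike, and the maturing hair cell median lay 0.96 above theirs. That gap cannot decide, since the supporting cell list shares Lfng, Hes5 and Hey2 with the Notch targets. In the samples numbered 1, bone and cartilage (-2.22), macrophage (-2.01) and mesenchyme (-0.85) medians were lower. Erythroid (0.92), muscle (0.35) and neutrophil (0.10) medians were higher there. In samples 2 and 3 the bone, macrophage and mesenchyme medians were -0.14, -0.11 and 0.02, while the maturing hair cell median was 0.66. Endothelial (0.12), neuronal (0.29), glial (0.62) and muscle (0.20) medians were higher there. Osteoclast (-0.70), neutrophil (-0.28) and erythroid (-0.23) medians were lower. These values argue against a general loss of surrounding tissue in samples 2 and 3. In the samples numbered 1 less surrounding tissue stays open. Control sample 1 alone does not set the hair cell difference, since the maturing median in samples 2 and 3 was 0.66. With samples 2 and 3 averaged, which leaves 2 values per group, 0 genes passed singly, while both hair cell lists still passed camera at the preset correlation. The correlation estimated from the data was higher, at 0.24 for the early list and 0.19 for the maturing list. At the preset correlation camera takes genes as nearly independent, so passing there cannot decide whether samples share a pool. Libraries of 1 pool counted as separate samples thus stay open for the single genes and for the lists. A hypothesis, not tested further, is a larger share of hair cells or more of these transcripts per cell after loss of Notch1.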

How the results depend on the processing

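The batch term, the averaged samples, samples 2 and 3 alone, the reduced rows and leave-one-out for lists were chosen after the data were seen. Called genes that stayed past the threshold kept their direction under each setting compared. Averaging leaves fewer samples. With samples 2 and 3 alone, the p-values rest only on the spread between these near-alike samples. The robust SD of their log2 difference was 0.0744 to 0.131, against 0.287 to 0.438 to sample 1. Passing the threshold there is thus no added support where the samples share a pool. For the other shifts the cause was not tested. Where 6 values stand together, they follow the order of the results. The number of changed genes with the replicate block was 635, 237, 2934, 826, 2290 and 53. It was 943, 370, 3569, 1371, 2814 and 177 with a batch term for sample 1. Under the averaging of samples 2 and 3 it was 10, 0, 259, 0, 175 and 0. It was 5685, 1735, 6134, 4281, 6189 and 2810 with the use of samples 2 and 3 alone. Under a model of the 2 groups alone it was 65 for β-catenin OE against Control, 8 for Notch1 KO against Control and 228 for the double group against β-catenin OE. It was 183 for β-catenin OE against Control, 73 for Notch1 KO against Control, 720 for the double group against Control, 167 for the double group against β-catenin OE and 590 for the double group against Notch1 KO with a change of at least 2-fold. Under pseudocount 0.1 it was 1 for the interaction. It was 7 for the interaction with no filter on low values. Under quantile normalization it was 6 for the interaction. Leaving out each sample, it ranged from 126 to 901 for β-catenin OE against Control, 14 to 213 for Notch1 KO against Control, 1128 to 2498 for the double group against Control, 113 to 1023 for the double group against β-catenin OE, 790 to 2060 for the double group against Notch1 KO and 0 to 67 for the interaction. The replicate block kept 325, 121, 1820, 393, 1467 and 3 of the calls in the same order.

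The number of lists past the threshold with estimated inter-gene correlation was 1, 4, 1, 0, 1 and 0. It was 3, 6, 10, 7, 7 and 1 with fry. Under fry in either direction it was 8 for Notch1 KO against Control, 26 for the double group against Control, 23 for the double group against Notch1 KO and 6 for the interaction. Leaving out each sample, it ranged from 7 to 16 for Notch1 KO against Control and 9 to 20 for the double group against Control. Calls shared by β-catenin OE and the double group against Control numbered 524 with the replicate block, 725 with a batch term for sample 1, 10 with the averaging of samples 2 and 3 and 3584 with the use of samples 2 and 3 alone, and 118 to 723 leaving out each sample. The log2 fold change of Notch1 with the replicate block was -1.11 for Notch1 KO against Control, past the threshold. It was -1.11 for Notch1 KO against Control, past the threshold, with a batch term for sample 1. Under the use of samples 2 and 3 alone it was -0.99 for Notch1 KO against Control, -0.38 for the double group against Notch1 KO and -0.43 for the interaction, past the threshold. It was -1.41 for the double group against Control and -1.74 for the double group against β-catenin OE, where both calls ended, with the averaging of samples 2 and 3. Under a model of the 2 groups alone it was -1.64 for the double group against β-catenin OE, where the call ended. Leaving out each sample, it ranged from -1.26 to -0.91 for Notch1 KO against Control and -1.85 to -1.24 for the double group against β-catenin OE. The log2 fold change of Ctnnb1 with the use of samples 2 and 3 alone was 0.15 for β-catenin OE against Control, 0.36 for the double group against Control, 0.22 for the double group against β-catenin OE, 0.33 for the double group against Notch1 KO and 0.19 for the interaction, past the threshold.

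Using samples 2 and 3 alone, the median changed sign in 42 of 198 list results, 10 of them past the threshold with all samples. Camera's direction changed in 13 results past the threshold with all samples or with these, whose medians became 0.29 for spiral ganglion neuron in Notch1 KO against Control, 0.62 for Schwann and myelinating glia in Notch1 KO against Control, 0.022 for mesenchyme and fibroblast in Notch1 KO against Control, 0.12 for endothelial and pericyte in Notch1 KO against Control, -0.23 for erythroid in Notch1 KO against Control, 0.028 for spiral ganglion neuron in the double group against Control, 0.26 for Schwann and myelinating glia in the double group against Control, -0.12 for S phase in the double group against β-catenin OE, -0.34 for G2M phase in the double group against β-catenin OE, -0.29 for interferon response in the double group against β-catenin OE, -0.10 for S phase in the interaction, -0.65 for G2M phase in the interaction and -0.31 for interferon response in the interaction. Depth is unknown for the samples numbered 1, which limits what low genes can show there.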

Other observations

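In the double group against Control, among genes in none of the fixed lists, Bpifb5 (4.99 ± 0.31), Dcpp2 (5.05 ± 0.58) and Aldh1a3 (4.87 ± 0.55) rose, and Slc22a3 (-3.98 ± 0.22) fell (n = 3 per group). In the list of Wnt ligands, receptors and core components, of 43 tested members, 7 rose, 9 fell and 27 did not pass, and adjusted over the list alone, 7 rose and 12 fell, with the ligands Wnt6 (2.64 ± 0.27) and Wnt10a (4.36 ± 0.63) among those that rose. The list did not pass camera's test (adjusted p = 0.84), and its median was -0.10 where its mean was 0.0853.

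Sex-linked genes, chosen after their values were seen, differed between samples. The Y-linked gene Ddx3y was listed at 0 in sample 1 of Control and β-catenin OE and at 0.00822 FPKM in Notch1 KO sample 1. It had 11.5 FPKM in double sample 1 and 12.6 to 24.3 in the 8 samples numbered 2 and 3. Double sample 1 thus differed in Ddx3y from sample 1 of every other group, and double samples 2 and 3 differed in Xist from Control. The sex of the pools is therefore not balanced in the comparisons of the double group, and what it adds to their calls was not tested. In Control, β-catenin OE and Notch1 KO, sample 1 differed in Ddx3y from samples 2 and 3. In the double group sample 1 differed from samples 2 and 3 in Xist. These values argue against sample 1 of a group coming from the same pool of animals as samples 2 and 3. They do not decide whether samples 2 and 3 share a pool.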
